A study of Mus musculus with 2 samples.

How the data were processed

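DNase-seq was carried out on lung of 2 female B6CASTF1/J mice at 14 days of age, 1 library per animal, with the animals numbered 5 and 6 as replicates 1 and 2 of a single group. For each library the authors deposited 2 peak lists, a table of the false discovery rate of the cut rate along the genome, and a list of footprints, all made for each library from its own alignment to mm10 without pooling of replicates. All 3 kinds of file also had inputs that are named only by accession, so they are not known to rest on the alignment alone. The aligner, the peak and footprint callers and their versions were not given in the sources used here. The deposited peak signal is a scaled read density of each peak whose scale is not stated. Its values were whole multiples of 1 step per library in 100% of the values tested, within a tolerance of 0.1 steps, so each library had a single scale factor, which may or may not be its depth. The p-value column in the deposited tables of the cut rate is a false discovery rate per stretch of bases, listed only below 0.05. In the deposited footprint lists the p-value column is the constant 0.01, a threshold rather than a score.

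The longer peak list was used throughout and the shorter one as an alternative. Every peak of the longer lists held a stretch with a false discovery rate of at most 0.05 and every peak of the shorter lists one of at most 0.001, and 69.4% and 68.9% of the peaks of the longer lists reached 0.001. Overlapping peaks of 1 list were merged, from 182923 to 181681 in replicate 1 and from 128390 to 127516 in replicate 2, and the highest signal was kept. No summit was given, so peak centres were used. The smallest step of the signal was 0.00685 in replicate 1 and 0.00538 in replicate 2, which corresponds to 146 and 186 M reads (M, mega) only if the scale was counts per M reads. Intervals on shares are 95% exact binomial intervals and cover counting error only, since reads and neighbouring peaks are not independent molecules or sites.

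Genes, transcripts and transcription start sites came from the basic annotation of GENCODE mouse release 21, and sequence came from the matching GRCm38 assembly, the build called mm10 in the files. For genes and gene lists, a promoter peak lay within 500 bp of a start site of a protein-coding transcript, or of Xist. For all other results it lay within 500 bp of any start site. A distal peak lay over 1 kb from any start site and, where counted for a gene, within 50 kb of the gene's own. The remaining peaks were placed in exons, introns or intergenic DNA by their centre. All 21851 protein-coding genes formed the background. The 30 gene lists were tested by two-sided permutation over genes against 100000 random lists of the same size, matched on decile of promoter CpG observed over expected for promoters and on decile of GC content in 100 kb for distal peaks. The smallest p these permutations can give is 2e-05. The p-values were adjusted by Benjamini-Hochberg over the 30 lists in each animal, and a list was called only where the adjusted p was under 0.05 in both animals in the same direction. In these tests genes are the units, so they say nothing of variation between animals, and the members of a list do not vary independently.

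In 1 simulated animal with independent genes, lists of 15 genes were tested at an adjusted p under 0.05. Among promoter lists, 8 of 10 with every promoter open, 5 of 5 with none open and 1 of 15 unchanged lists passed. Among distal lists, 10 of 10 with doubled counts and 0 of 20 unchanged ones passed. The rule of passing in both animals and lists of clustered genes were not simulated. Motif families were consensus strings searched within 75 bp to each side of the centre of distal peaks and in windows 1 kb to each side, with up to 20 shuffled strings of the same composition as the reference and a pseudocount of 0.5 on counts. Overlap of peaks between animals was set against 100 random circular shifts. Each footprint was instead placed at random within its stretch shared by both animals, 100 times and independently of the others. The genes named were 40 fixed genes, the 3 genes with the highest mean promoter signal in each list called higher in both animals, and the 10 shared distal peaks with the highest mean signal, with their nearest gene. A list called higher in promoters or in distal peaks counted under this rule. The gene lists, the 40 genes, the motif families, the tests and all alternatives were chosen before the data were examined, except the lists with 1 gene per 100 kb, the overlap of the 10000 strongest peaks and the comparisons of the 2 animals in the closing observations.

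Alternatives were the shorter peak list, the same number of top peaks in both animals, a reciprocal overlap of at least 50%, wider and narrower windows, 1 start site per gene, no matching, mean log2(signal + 1) in place of the share of open genes, shared distal peaks for motifs, and leaving out each animal. The stricter part of the footprints by score was not run, since the score is constant. Allele-specific accessibility, which a hybrid cross would allow, was not analysed here, since it needs reads. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures matplotlib 3.10.9.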

Results

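DNase-seq, which reads the ends of DNA fragments cut by DNase I and so maps chromatin that is accessible to the enzyme, was measured in lung from 2 female B6CASTF1/J mice, the F1 hybrid of C57BL/6J and CAST/EiJ, at 14 days of age. Both animals belonged to 1 group, so the data allowed a comparison of replicates and a description of the accessible sites of the lung, but no contrast between conditions and no test over animals. After overlapping peaks had been merged, the longer of the 2 deposited peak lists held 181681 peaks over 34.5 Mb in replicate 1 and 127516 peaks over 25.4 Mb in replicate 2, on the mm10 build. The depth was not given. If the peak signal was scaled as counts per M reads, its smallest step corresponded to 146 M reads in replicate 1 and 186 M reads in replicate 2 (M, mega), and the median peak rested on 94 and 102 reads. The number of peaks allowed narrow counting intervals for shares of peaks, but 2 animals gave only a coarse measure of the spread between animals.

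The 2 lungs shared most of their strong accessible sites. Of the 10000 peaks with the highest signal, 99.5% in replicate 1 and 99.9% in replicate 2 overlapped a peak of the other animal, a comparison added after the data had been seen. Among all peaks, 61.1% of those in replicate 1 (95% exact binomial interval 60.9 to 61.3%) and 86.7% of those in replicate 2 (86.5 to 86.9%) overlapped a peak of the other animal by at least 1 bp. When the peaks were moved by random circular shifts within chromosomes, the highest shares in 100 shifts were 2.05% and 2.92%. The peaks without a partner were weak: in replicate 1 their median signal was 0.363 (70644 peaks), against 1.06 for shared peaks, and in replicate 2 it was 0.317 (16971 peaks), against 0.619.

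At the 109993 shared peaks, signal ranked similarly in both animals, with a Spearman rho of 0.832 across peaks, which are not independent replicates. The rank correlation was 0.963 at the 22595 shared promoter peaks and 0.762 at the 82159 shared distal peaks, those over 1 kb from any transcription start site. Signal was lower in replicate 2 at 87.6% of shared peaks, by a median of 1.64-fold, with an SD of the log2 difference of 0.63. Signal levels and peak numbers are therefore given for each animal below, and gene lists were called only where both animals passed the test in the same direction.

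**Figure D1:**
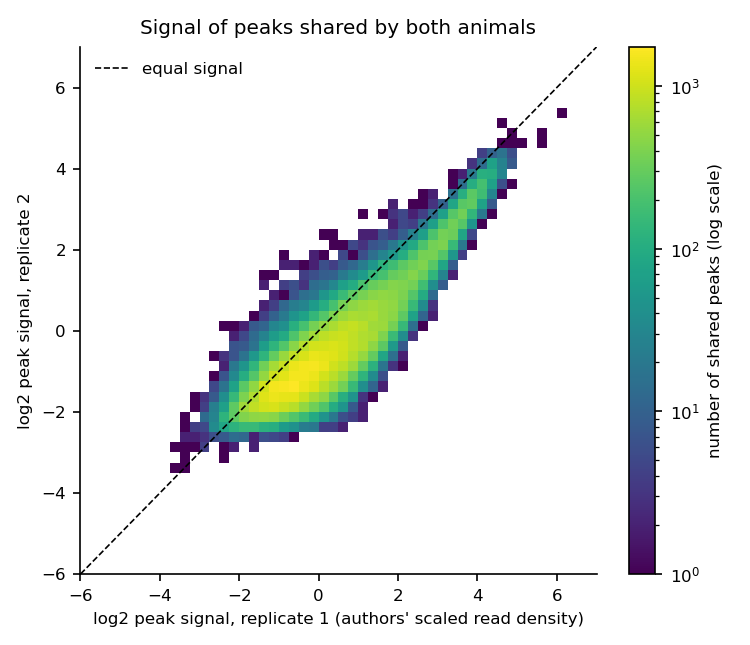
Log2 peak signal in replicate 2 (vertical axis) against replicate 1 (horizontal axis) for the 109993 shared peaks, in the authors' scaled read density, with colour giving the number of peaks per bin on a log scale. The dashed line marks equal signal, and 87.6% of the peaks lie below it.

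Most accessible sites of the lung lay away from promoters. Introns held 45.3% of peaks in replicate 1 and 43.7% in replicate 2, intergenic DNA held 33.8% and 32.1%, and exons held 4.90% and 4.94%. Stretches within 500 bp of a transcription start site held 16.02% (95% exact binomial interval 15.85 to 16.19%) and 19.26% (19.05 to 19.48%), a mean of 17.6% ± 2.29 (SD, n = 2).

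Peak density differed between chromosomes. Autosomes held 71.9 peaks per Mb in replicate 1 and 50.6 in replicate 2. Chromosome 11 was the densest, with 103.4 and 75.6 peaks per Mb, and the X chromosome held 26.4 and 16.8, or 0.366 and 0.331 of the autosomal density. The Y chromosome held 26 and 43 peaks, of which 19 and 30 lay in sequence that was soft-masked as repeats over most of its length. The strongest Y peak lay mostly outside repeats: it spanned 90744501 to 90744740 in replicate 1, with a signal of 3.30 and 0% soft-masked, and 90744521 to 90744820 in replicate 2, with 1.43 and 10.3%. Whether its reads came from the Y chromosome or from similar sequence elsewhere, such as on the X chromosome, was not tested. No peak lay at the promoters of the Y-linked genes Ddx3y, Kdm5d, Uty or Eif2s3y in either animal. The promoter of Xist, whose RNA coats the inactive X chromosome in females, carried a peak in both, with a signal of 1.79 in replicate 1 and 0.861 in replicate 2.

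Promoters of genes that mark the cells of the alveolar wall were open in both lungs. In the list of alveolar type 2 cells, which secrete surfactant, 18 of 19 genes had a promoter peak in each animal (94.7%), against 45.4% and 41.6% in random lists matched on promoter CpG content. In the endothelial list it was 26 of 27 genes in each animal (96.3%, against 64.1% and 58.6%). In the list of smooth muscle and pericytes it was 22 of 22 genes in replicate 1 and 19 of 22 in replicate 2 (100% and 86.4%, against 63.7% and 57.7%). These 3 lists were the ones called higher among the 30 tested.

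Ranked by the mean of both animals, the highest promoter signals of the alveolar type 2 list were at Etv5, a transcription factor of these cells, at 17.3 in replicate 1 and 15.6 in replicate 2, at the lipid transporter gene Abca3, at 9.43 and 6.08, and at Cebpa, at 9.57 and 5.24. The surfactant protein genes had lower signals: Sftpc had 1.86 and 1.79 (mean 1.83 ± 0.05 SD, n = 2) and Sftpb had 1.79 and 1.495. Of the list, only Hc, which encodes complement component C5, lacked a promoter peak in both animals. In the endothelial list the highest mean signals were at the receptor genes Calcrl, at 5.33 and 2.46, and S1pr1, at 4.18 and 2.51, and at the adhesion gene Esam, at 4.41 and 2.29, but this order was not that of replicate 2, in which Clec14a, at 3.25, was the highest. The junction genes Cdh5 and Pecam1 had 2.90 and 2.53, and 1.57 and 1.20. The transcription factor genes Erg and Sox17 had 1.11 and 0.828, and 1.31 and 0.688. In the list of smooth muscle and pericytes they were at Smtn, at 10.6 and 5.17, Myh11, the smooth muscle myosin heavy chain, at 5.83 and 2.62, and Gucy1b1, a subunit of the nitric oxide receptor, at 3.70 and 1.94, while Acta2 had 1.17 and 0.887.

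Promoters of genes that mark other organs were open less often than matched ones in 3 lists. None of 10 genes of retina and lens had a promoter peak in either animal, against 49.3% and 43.8% in matched lists. In the testis list 2 of 10 genes had one in replicate 1 and 1 of 10 in replicate 2, against 56.3% and 51.1%: the germ cell gene Dazl, with a signal of 5.97 and 3.48, and Sycp3, with 0.226 in replicate 1 alone. Hox genes of paralog groups 9 to 13, which pattern the posterior body, had promoter peaks at 4 of 16 genes in replicate 1 and 3 of 16 in replicate 2, against 90.9% and 86.9%. Of these, Hoxa10 had 2.97 and 1.01, Hoxc10 had 1.31 and 0.834, Hoxc13 had 1.03 and 0.344, and Hoxd10 had 0.582 in replicate 1 alone; all 4 were named after their values had been seen, as were Hc, Dazl and Sycp3. Hox paralogs 1 to 5 had peaks at 9 of 15 genes in each animal and were not called, with Hoxa5, which acts in lung development, at 6.06 and 3.87.

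The adjusted p of the called lists came from two-sided permutation tests in which genes, not animals, were the units. In replicates 1 and 2 it was 0.0002 and 0.0002 for alveolar type 2, 0.0003 and 0.0002 for endothelium, and 0.0002 and 0.0118 for smooth muscle and pericytes. It was 0.0036 and 0.0118 for retina and lens, 0.0437 and 0.0122 for testis, and 0.0002 and 0.0002 for Hox paralogs 9 to 13. The calls of the Hox and testis lists ended in permutation tests that kept 1 gene per 100 kb, with adjusted p of 0.0359 and 0.063 (4 Hox genes) and of 0.084 and 0.0342 (8 testis genes); the differences from matched lists were then -62.7 and -57.9 percentage points for Hox, against -65.9 and -68.2 with all genes, and -36.7 and -43.9 for testis, against -36.3 and -41.1. With the mean log2 signal in place of the share of open genes, the endothelial list was no longer called (adjusted p of 0.229 and 0.105), nor was that of smooth muscle and pericytes (0.536 and 0.953, with a difference of 0.17 and -0.02), which also lost its call with the shorter peak list (0.0098 and 0.215) and without matching (0.0026 and 0.0705).

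Lists of other lung cell types did not pass the promoter test in both animals, and some lay below their matched share. Capillary subtypes had 12 and 11 open genes of 12 and fibroblasts 22 and 20 of 24, and both passed in replicate 1 (adjusted p of 0.0495 and 0.0273) but not in replicate 2 (0.149 and 0.0852). Alveolar type 1 cells, the flat cells of gas exchange, had 17 of 18 in each animal, against 82.4% and 77.3% in matched lists. By mean log2 signal, the differences of the type 1 list (-0.59 and -0.36) and of the fibroblast list (-0.25 and -0.35) were negative, and neither passed. The type 1 list was called higher without matching (26.6 and 30.5 percentage points, adjusted p of 0.0321 and 0.0192), and the fibroblast list with the most upstream start site of each gene (24.3 and 21.1 points, 0.0075 and 0.0366). Shared epithelial genes had 18 and 16 of 19, secretory airway genes 5 and 4 of 10, ciliated cell genes 15 and 14 of 19, basal cell genes 4 and 3 of 8, neuroendocrine genes 7 and 5 of 10, and lymphatic genes 6 and 4 of 8. Elastic fibre genes had 11 and 8 of 13, mesothelial genes 5 and 3 of 9, myeloid genes 12 and 10 of 22, and lymphoid genes 13 and 12 of 20. Basal genes were at 50% and 37.5%, against 51.1% and 45.2% in matched lists, and neuroendocrine genes at 70% and 50%, against 87.1% and 81.9%. Lymphatic genes were at 75% and 50%, against 75.3% and 71.5%, and mesothelial genes at 55.6% and 33.3%, against 62.9% and 58.4%. These lists lay below their matched shares in both animals, and the other lung lists above theirs. Among blood cell and other organ lists, erythroid genes had 1 and 0 open promoters of 10, liver 3 and 1 of 18, kidney 3 and 2 of 12, intestine 2 and 2 of 10, pancreas 5 and 3 of 12, epidermis 1 and 1 of 8, and heart muscle 5 and 5 of 13. Skeletal muscle (3 and 1 of 14) and neurons (7 and 4 of 13) were lower in replicate 2 alone, and all 20 housekeeping genes were open in both animals.

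Distal accessible sites were dense around genes of endothelium, alveolar type 1 cells, fibroblasts and smooth muscle. Genes of the endothelial list had 13.7 distal peaks within 50 kb in replicate 1 and 10.9 in replicate 2, or 1.65 and 1.78 times the number in random lists matched on GC content (mean 1.71 ± 0.09 SD, n = 2), and 25 of 27 genes lay above the matched mean in both animals. Alveolar type 1 genes had 14.1 and 11.1 peaks, or 1.66 ± 0.07 times the matched number, with 14 of 18 genes above it in both. Fibroblast genes had 11.4 and 7.29, or 1.52 ± 0.15 times, with 18 of 24 above it, and genes of smooth muscle and pericytes had 11.1 and 8.27, or 1.40 ± 0.01 times, with 13 of 22 above it. Hox paralogs 9 to 13 had 6.25 and 3.75 peaks, 0.504 ± 0.087 times the matched number, which made them the only list called lower. Sequence within 1 kb of any start site cannot hold a distal peak, and random lists were not matched on the sequence left to count. The 16 Hox genes are clustered (4 remain with 1 gene per 100 kb). Their low number may therefore follow from this definition, which was not tested.

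In replicates 1 and 2 the adjusted permutation p was 0.0002 and 0.0003 for endothelium, 0.0002 and 0.0012 for alveolar type 1, 0.0002 and 0.0459 for fibroblasts, 0.0102 and 0.0459 for smooth muscle and pericytes, and 0.0003 and 0.0003 for Hox paralogs 9 to 13. The endothelial call held in every alternative. The alveolar type 1 call ended within 20 kb (adjusted p of 0.0113 and 0.0913). In replicate 2 the fibroblast list missed the threshold with 1 gene per 100 kb (0.067), without matching (0.212), with the shorter peak list (0.140), within 100 kb (0.066) and within 20 kb (0.075), and so did that of smooth muscle and pericytes with 1 gene per 100 kb (0.067), without matching (0.07) and within 100 kb (0.066); within 20 kb that list missed it in both animals (0.144 and 0.187). The Hox call ended without matching (0.458 and 0.278), where the difference shrank from -4.81 and -4.72 peaks per gene to -1.29 and -1.76, and with 1 gene per 100 kb (0.263 and 0.197), where 4 genes gave -4.18 and -3.92. Alveolar type 2 genes passed in replicate 2 alone (1.27 and 1.48 times the matched number, adjusted p of 0.141 and 0.0171), and capillary subtype genes in replicate 1 alone (1.54 and 1.31 times, 0.00888 and 0.253). Neuron genes (0.722 and 0.518 times) and Hox paralogs 1 to 5 (0.856 and 0.662 times) were lower in replicate 2 alone, and the other 21 lists passed in neither animal.

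**Figure D2:**
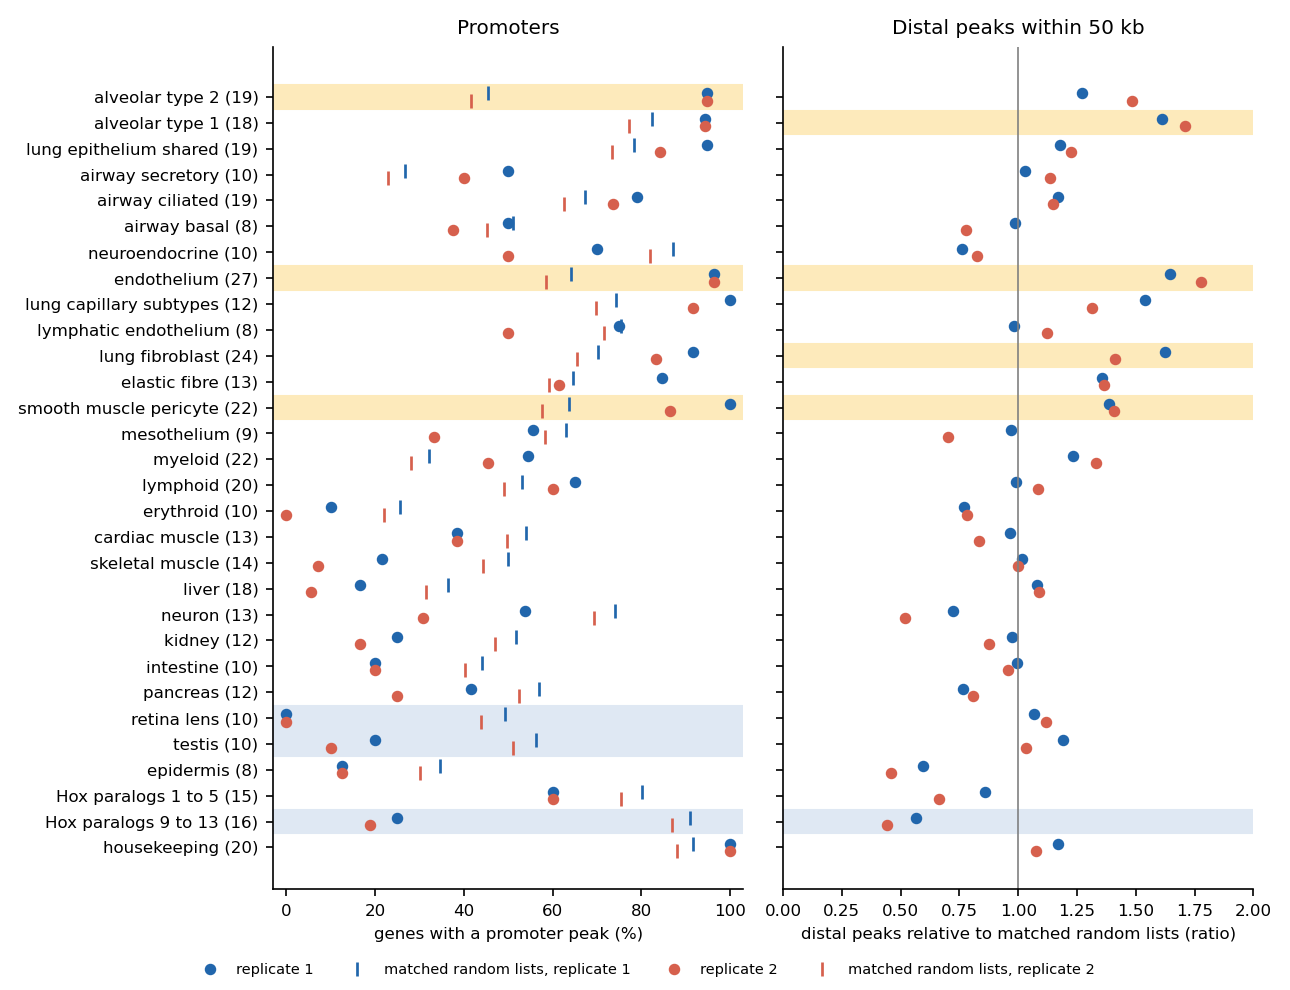
Each line is a gene list with its number of genes. Points give, for replicates 1 and 2, the share of genes with a promoter peak in percent (left) and the ratio of distal peaks within 50 kb to that of matched random lists (right), and vertical ticks on the left give the matched random share. Yellow bands mark lists called higher in both animals and blue bands lists called lower: 94.7% of alveolar type 2 genes were open, and retina and lens genes were at 0%.

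Of the epithelial regulators, Nkx2-1, the transcription factor of lung identity, had a promoter signal of 2.61 and 1.53 but only 2 and 1 distal peaks within 50 kb, and Foxa2 had 1.61 and 1.05 with 7 and 7. Among genes of the alveolar type 1 list, the promoter signal in whole lung was 3.53 and 2.07 at Hopx, 2.08 and 1.62 at Ager, 6.87 and 2.81 at the angiogenic factor gene Vegfa, and 5.50 and 2.98 at Rtkn2. Distal peaks numbered 17 and 13 around Hopx, 12 and 15 around Ager, 16 and 15 around Sftpb, and 9 and 6 around Abca3. Among airway genes, the ciliated cell regulator Foxj1 had a strong promoter peak (10.9 and 5.38), while the club cell secretory protein gene Scgb1a1 had none in either animal but 16 and 13 distal peaks. Trp63, a regulator of basal cells, had a promoter signal of 0.240 in replicate 1 and no peak in replicate 2, with 3 and 3 distal peaks.

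Over all protein-coding genes, the mean number of distal peaks within 50 kb was 7.54 in replicate 1 and 5.52 in replicate 2. Among endothelial genes, 24 and 19 distal peaks lay around Cdh5, 15 and 11 around Pecam1, 7 and 3 around Erg and 9 and 4 around Sox17. Erg lay below that mean in both animals, and Sox17 in replicate 2. The capillary genes Aplnr and Car4 had 17 and 13, and 16 and 10. Aplnr had a promoter signal of 1.35 and 0.957, Car4 had 0.472 in replicate 1 and no peak in replicate 2, and the lymphatic regulator Prox1 had 1.83 and 0.629 with 6 and 6 distal peaks. Among mesenchymal genes, the transcription factor genes Tbx4 and Foxf1 stood in dense stretches of 25 and 15, and 21 and 14 distal peaks, with promoter signals of 2.07 and 1.43, and 4.04 and 3.15. Tcf21 had 1.94 and 1.11 with 11 and 5 distal peaks, Pdgfra had 4.11 and 1.38 with 12 and 6, and Gli1 had a promoter signal of 4.89 and 1.59. Eln, which encodes elastin, had 9.23 and 6.30 with 21 and 18 distal peaks, Acta2 had 17 and 9 distal peaks and Myh11 had 9 and 3. Wt1, a mesothelial regulator, had 0.329 in replicate 1 alone and 4 and 1 distal peaks.

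Among immune genes, Ptprc, which encodes CD45, had a promoter signal of 0.520 and 0.506, and the B cell regulator Pax5 had 0.397 and 0.441, with 9 and 4, and 9 and 10 distal peaks. The myeloid regulator Spi1 and the T cell gene Cd3e had no promoter peak, with 16 and 10, and 4 and 5 distal peaks. Regulators of other lineages had no promoter peak in either animal: Gata1, Hnf4a, Neurod1, Myod1, Cdx2, Pdx1, Nkx2-5 and Hoxa13. Distal peaks nevertheless lay within 50 kb of each of them, from 16 and 9 around Hnf4a and 12 and 9 around Cdx2 to 2 and 1 around Neurod1. The counts around Hnf4a and Cdx2 lay above the mean of all protein-coding genes, 7.54 and 5.52. Alb, which encodes serum albumin, had a promoter signal of 0.157 in replicate 1 alone. The absence of a listed peak means that none passed the authors' threshold, not that the promoter was closed in every cell.

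**Figure D3:**
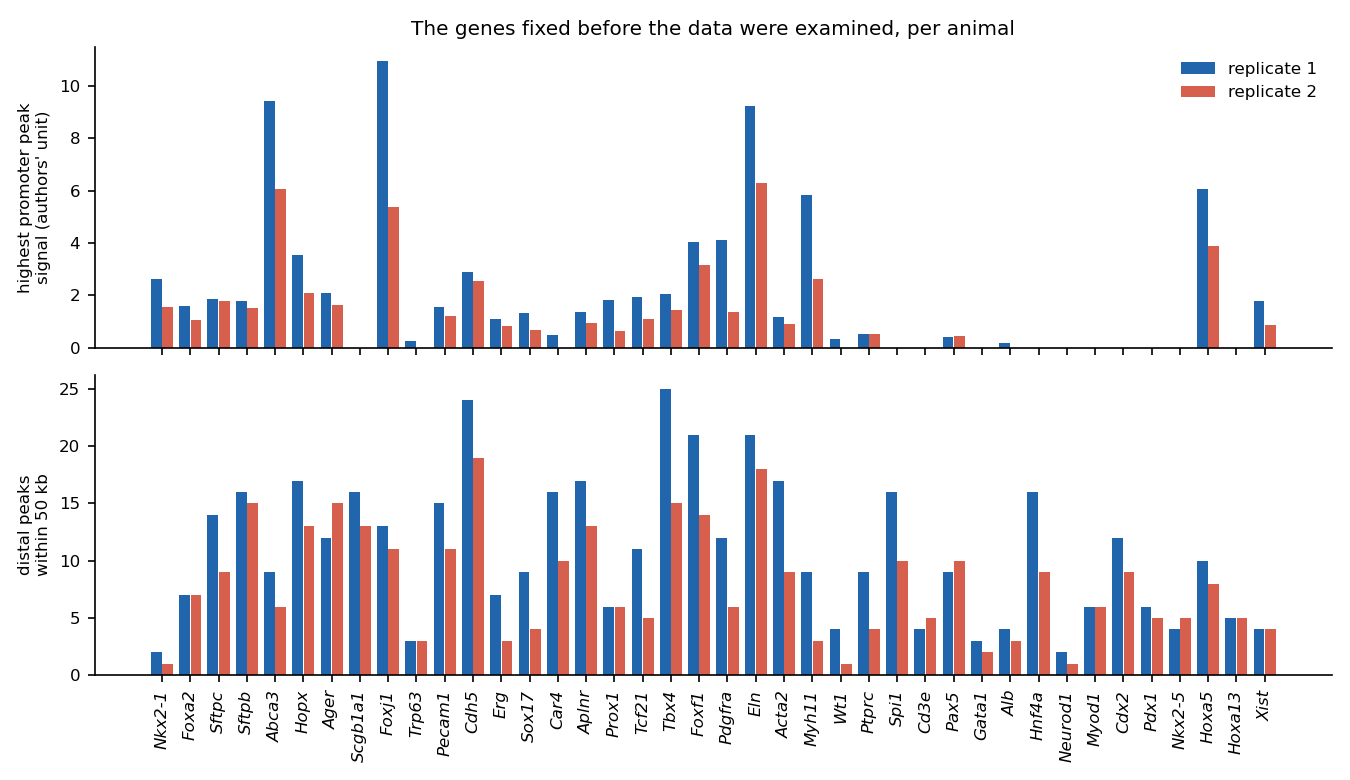
Highest promoter peak signal (top, authors' scaled read density) and number of distal peaks within 50 kb (bottom) of the 40 genes fixed before the data were examined, as 1 bar per replicate. The tallest promoter bars are at Foxj1 (10.9 and 5.38), Abca3 (9.43 and 6.08) and Eln (9.23 and 6.30), and genes of other lineages such as Gata1 have none.

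Around Sftpc, which encodes surfactant protein C and lies on the minus strand of chromosome 14 from 70520949 to 70524081, accessible sites recurred in both lungs. Within 25 kb to each side there were 16 peaks in replicate 1 and 13 in replicate 2, of which 12 were shared. The promoter peak spanned 70524081 to 70524480 in replicate 1, with a signal of 1.86, and 70524121 to 70524380 in replicate 2, with 1.79. A pair of intergenic peaks upstream was as strong: 70526641 to 70527020 with 1.98 and 70527121 to 70527320 with 2.99 in replicate 1, and 70526681 to 70527060 with 1.69 and 70527061 to 70527320 with 1.76 in replicate 2. The strongest promoter peak nearby belonged to the neighbouring gene Reep4, with 8.91 and 3.97.

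**Figure D4:**
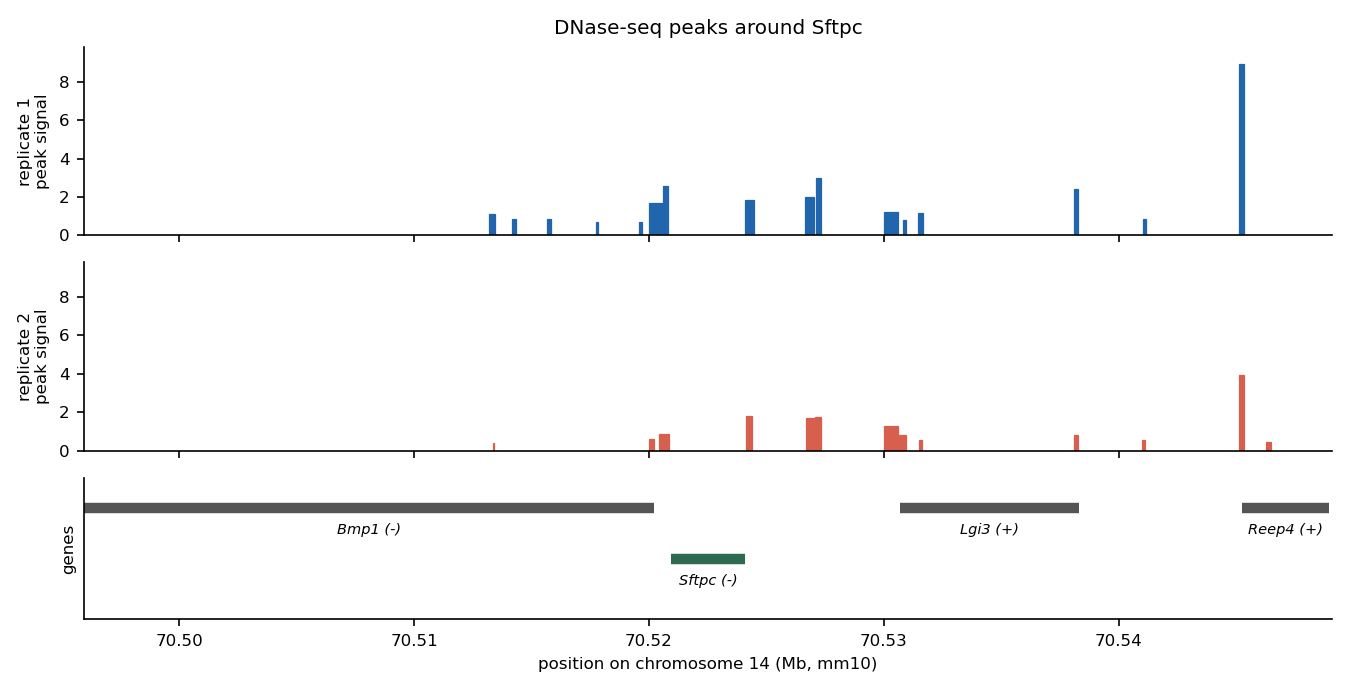
Peaks within 25 kb of Sftpc on chromosome 14 (mm10, position in Mb) in replicate 1 (top) and replicate 2 (middle), with bar width giving the peak's span and height its signal in the authors' unit. Protein-coding genes and their strands are drawn at the bottom, and the promoter peak of Sftpc reaches 1.86 and 1.79.

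None of the 10 strongest shared distal peaks had a gene of the 30 lists as its nearest gene. The nearest gene was the protein-coding gene whose most upstream start site lay closest to the peak centre. The highest peak was intergenic, on chromosome X at 143482981 to 143483140, with a signal of 66.0 and 40.3. It lay 35531 bp from that start site of its nearest gene, Pak3. On chromosome 15, a peak in an exon of Cers5 at 99735641 to 99735920, nearest to the start of Cox14, had 23.3 and 35.4. On chromosome 9, a peak near Gm10722 at 3002041 to 3002220, which was wholly soft-masked repeat, had 24.4 and 21.4, and a peak in an exon of Lars2 at 123461921 to 123462100, nearest to Limd1, had 26.0 and 18.2. The other 6 were nearest to Fbrs, Tfap4, Gm21887, Igf2bp3, Morn3 and Idnk, with mean signals of 18.0 to 20.5, and the peak nearest to Gm21887 lay in an intron of Mid1. No peak was left out here for repeats or mappability, and whether all 10 are accessible sites was not tested.

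Distal accessible sites carried the sequence motifs of a broad set of transcription factor families. Of 28 families, 17 had a log2 ratio of distal peaks to flanking windows above that of every shuffled string in both animals, and 14 of these were also more frequent in peaks than in flanks in both. CTCF, the insulator protein, matched 4.37% of 143665 distal peaks in replicate 1 and 4.78% of 96694 in replicate 2, 4.57 and 4.66 above the shuffled mean on the log2 scale. NFI, a family that acts in lung maturation, matched 2.81% and 2.15% (2.58 and 2.19 above), and the families linked to endothelium and blood, ETS and PU1, matched 4.18% and 4.52% (1.44 and 1.499) and 3.87% and 4.39% (1.43 and 1.57).

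TEAD, the partner of YAP, was 1.19 and 1.42 above the shuffled mean, AP1 was 0.96 and 1.12, and FOX was 0.88 and 1.09. NKX2, the family of Nkx2-1, was 0.75 and 0.85 above it, CEBP 0.73 and 0.85, STAT 0.90 and 0.98, and the E-box CAGCTG 1.05 and 0.98. RFX also passed, as did REST, which matched 0.0863% and 0.0579% of distal peaks against 0.00139% and 0.00103% of flanks, but whose shuffled strings had too few matches to compare with. MEF2, IRF and HNF1 passed only because the ratios of their shuffled strings were lower still: their own log2 ratios of peaks to flanks were -0.79 and -0.83, -0.18 and -0.24, and 0.08 and -0.51. The glucocorticoid receptor motif passed with unequal sizes, 0.48 in replicate 1 and 1.83 in replicate 2, and no longer passed in windows of 50 bp to each side. The families that did not pass in both animals were KLF and SP, NRF1, GATA, OCT, RUNX, the E-box CAGATGG, GRHL, HNF4, NFY, SRF and SOX.

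Footprints, short stretches of fewer cuts within accessible sites, covered a part of these motifs. There were 419135 footprints in replicate 1 and 302797 in replicate 2, with a median width of 10 and 9 bp, and 87.9% and 89.3% of them lay in peaks. Within stretches shared by both animals, 52.9% of the footprints of replicate 1 and 62.0% of those of replicate 2 overlapped a footprint of the other. With each footprint placed at random within its stretch, the mean shares were 35.3% and 39.4%. A match was counted as in a footprint only where its centre base lay in one. Of the CTCF matches in distal peaks, 88.7% and 79.5% did so, against 22.4% and 17.9% of matches of shuffled strings.

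The other families above every shuffled string in both animals were NFI, with 64.8% and 62.2% of matches in footprints, NRF1, with 87.5% (77 of 88) and 88.6% (62 of 70), RFX, with 55.3% and 54.5%, NKX2, with 19.7% and 18.7%, SRF, with 16.4% and 14.6%, and IRF, with 10.95% and 12.06%, which is no more than the share of all distal peak bases in footprints in replicate 1 (13.7%) and near it in replicate 2 (11.6%). REST, with 79.2% and 58.6% of its 125 and 58 matches in footprints, also stood above its shuffled strings, but these had too few matches for the comparison to count. FOX matches lay in footprints in 5.97% and 5.36% of cases, against 7.82% and 7.09% for shuffled strings, and AP1, TEAD, ETS, PU1 and the glucocorticoid receptor motif did not pass either. No footprint score could be weighed, since the deposited score was the same, 0.01, for every footprint.

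**Figure D5:**
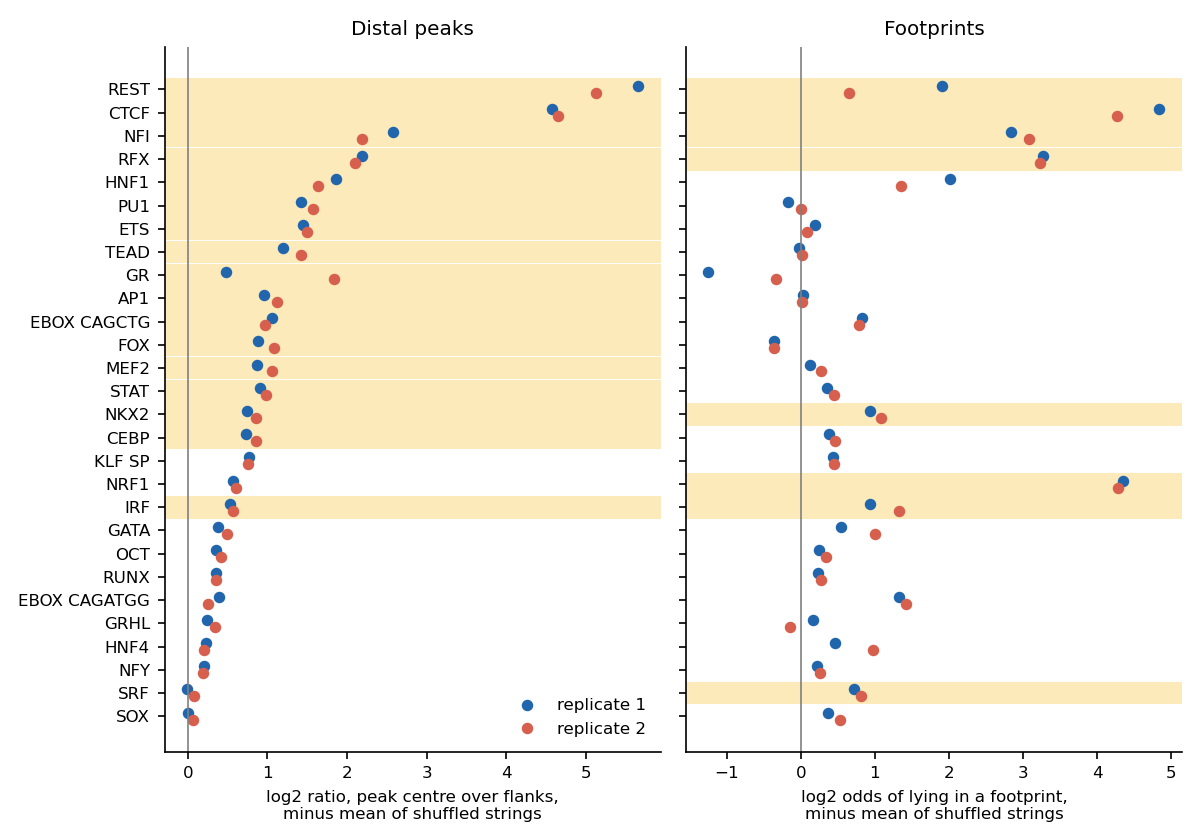
Motif families in distal peaks (left) and in footprints (right), as 1 point per replicate. Values on the left are the log2 ratio of peak centre to flanks minus the mean of shuffled strings. Those on the right are the log2 odds that the centre base of a match lies in a footprint, minus the mean of shuffled strings. Yellow bands mark families above every shuffled string in both animals, 17 in peaks and 8 in footprints (REST, with few shuffled matches, among them), with CTCF at 4.57 and 4.66 in peaks.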

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

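The lists with 1 gene per 100 kb and the overlap of the 10000 strongest peaks were chosen after seeing the data, and no called list reversed in the mean of both animals (smooth muscle and pericytes were at -0.02 in replicate 2 by mean log2 signal), while 32 values of lists called in neither setting changed sign. Overlap of replicate 1 and replicate 2 peaks was 52.1% and 74.2% with a reciprocal overlap of at least 50%, 61.4% and 88.8% with the shorter list, 78.02% and 77.79% with equal numbers of peaks, and 99.5% and 99.9% for the 10000 strongest. The rank correlation was 0.762 at distal and 0.963 at promoter peaks. With the shorter list 22.3% of peaks lay in promoters, 4.69% in exons, 41.8% in introns and 31.2% in intergenic DNA, and with promoters of 1000 bp 22.5%, 4.17%, 41.6% and 31.7%, a move that the wider window makes by its construction. Promoter lists called lower numbered 1 with 1 gene per 100 kb, 14 with mean log2(signal + 1), 5 with the most upstream start site, 9 without matching and 6 with the shorter list, and 3 to 5 with 1 animal left out (5 without replicate 1); those called higher numbered 3 to 5 (5 without replicate 2), 2 with mean log2(signal + 1), of which 1 was among the 3 lists called, and 2 with the shorter list. Distal lists called higher numbered 2 with 1 gene per 100 kb, within 100 kb and within 20 kb; those called lower numbered 0 with 1 gene per 100 kb (4 Hox genes) and without matching, and 1 to 3 with 1 animal left out (3 without replicate 1). With the shorter list 72.4% of footprints lay inside peaks, 63.9% of those in stretches shared by both animals overlapped one of the other animal, the X ratio was 0.322 and the Y peaks numbered 15 on average; with the longer list 39.5% of those in shared stretches overlapped reciprocally. The values that changed sign were, for promoters, differences in mean log2(signal + 1) of -0.47 (alveolar type 1), -0.21 (capillary), -0.31 (shared epithelium), -0.30 (fibroblast) and -0.40 (lymphoid), and differences in the share of open genes of -0.209 (secretory), -0.0334 (lymphoid) and -0.159 (myeloid) without matching, 0.0237 (basal) with 1 gene per 100 kb, 0.0128 (basal) with the most upstream start site and 0.0363 (neuroendocrine) within 1000 bp. For distal peaks per gene they were 1.16 (basal), 2.05 (heart), 1.11 (Hox 1 to 5), 1.33 (intestine), 0.563 (kidney) and -0.587 (lymphatic) without matching; -0.937 (secretory), 0.610 (erythroid), -0.455 (lymphatic), -0.535 (lymphoid) and -0.739 (skeletal muscle) within 100 kb; 0.439 (intestine), -0.387 (liver), 0.156 (mesothelium) and -0.612 (testis) within 20 kb; for skeletal muscle -0.553 with 1 gene per 100 kb, -0.477 with equal numbers of peaks and -0.00687 with the shorter list; and, with 1 animal left out, -0.120 to 0.582 (lymphatic), -0.0778 to 0.560 (lymphoid) and -0.00531 to 0.155 (skeletal muscle). Apart from fewer genes per list, a wider window and 1 animal in place of 2, the cause was not tested. Of 79 values of main results under alternatives 36 moved and 43 did not; of 480 for named genes 111 moved; of 510 for single lists 37 passed the test anew, 18 no longer did, 32 changed sign and 423 did neither; and of 224 for motif families 53 moved. Leaving out an animal gives no value for overlap or peak signal, and a stricter part of the footprints could not be formed from a constant score. For location, footprints, chromosomes, named genes and single motif families, the value of 1 animal always lies within the SD of both. Such values are counted above but could not move, so they say nothing of stability. With 2 animals the spread between animals is known only coarsely, and weak peaks, such as those not shared (median signal 0.363 and 0.317), are nearest to what depth can resolve.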

Other observations

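The gene groups described first and the patterns weighed after them were picked once the data had been seen; the 3 tests on peak number and those with 1 gene per 100 kb were chosen only after the result was seen, and the other tests were set before theirs was. The odorant receptor genes, which are expressed by sensory neurons of the nose, were nearly all without a promoter peak: 35 of 1134 had one in replicate 1 and 15 in replicate 2. Vomeronasal receptors had 7 and 2 of 331. Over all 21851 protein-coding genes the share open was 67.8% and 63.9%. Promoters of all 11 laminin genes, whose products build basement membranes, and of 15 of 17 Klf genes (88.2%) were open in both animals. Ribosomal protein genes (89.8% and 88.8%) and Zfp zinc finger genes (87.8% and 85.3%) lay near the share of Klf genes. Collagen genes, with 71.1% and 55.6%, lay near the share of all genes. None of these groups was matched on promoter CpG content, with which the share open rose steeply, so CpG content may account for their shares. The clustered protocadherins, which give neurons their cell identity, had 37 of 57 open promoters in replicate 1 and 13 in replicate 2. By mean number, the 5 genes with the most distal peaks within 50 kb were Trim8 (40 and 31 peaks), Kdm6b (40 and 28), Notch1 (37 and 31), E2f2 (32 and 33) and Thra (30 and 35), and promoter peaks covered 10.4% and 8.47% of genes in the lowest decile of CpG content against 97.3% and 95.9% in the highest.

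Each shared peak was set against the median of shared peaks of the same signal and GC decile, promoter peaks included. Distal peaks were then centred on their own mean. On this measure CTCF sites were weaker in replicate 2, with a mean log2 difference of -0.67 at 4721 peaks, below all 20 shuffled strings. They made up a larger share of the distal peaks of replicate 2 in the longer lists (4.78% against 4.37%). In the shorter lists they did not (6.19% against 6.27%). TEAD sites were stronger by 0.23, PU1 and ETS sites by 0.21 each and AP1 sites by 0.19, above all 20 shuffled strings in each case, as were GATA (0.15), FOX (0.13), NKX2 (0.12), CEBP (0.10) and MEF2 (0.05) sites, while the E-box CAGATGG, at -0.13, lay below all 20. No explanation of these values was tested.

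Replicate 2 had fewer peaks, 0.702 of the number in replicate 1. Whether depth, a lower share of reads at accessible sites or another mixture of cells lay behind this cannot be told apart, because the scale of the signal is not stated and each test below decides only if signal was scaled by total reads. On that scale replicate 2 would hold 1.27 times the reads of replicate 1, which would argue against lower depth. The median log2 difference of the 20 housekeeping promoters was -0.63 (interquartile range -0.74 to -0.43), with 19 of 20 lower in replicate 2, which on that scale would argue against the mixture as the whole cause and be consistent with a lower share of reads at accessible sites. No biological explanation was tested, since both animals carry the same labels.

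After correction for signal and GC content, shared peaks around some lists differed between the 2 animals relative to random genes. Here and for the receptor target genes below, random genes were matched only on their number of shared peaks. Neither this matching nor the correction took account of whether peaks were promoter, distal or CTCF peaks. Peaks were relatively stronger in replicate 2 around alveolar type 2 genes (log2 0.21), alveolar type 1 genes (0.21), shared epithelial genes (0.19, called only after the correction, since the raw adjusted permutation p was 0.0645) and endothelial genes (0.18, positive in 23 of 27 genes), and weaker around Hox paralogs 1 to 5 (-0.19) and 9 to 13 (-0.33), with adjusted permutation p of 0.003, 0.003, 0.00732, 0.0006, 0.0135 and 0.0006. That 6 of 30 lists passed after the correction argues against signal level or GC content as the whole cause; with 1 gene per 100 kb the 4 higher lists passed (adjusted permutation p of 0.0042 to 0.011) and the Hox lists, left with 4 genes each, did not (0.336 and 0.111), at differences of -0.21 and -0.36 that were no smaller. A different mixture of cells in the 2 pieces of lung could give such shifts, but no mesenchymal list passed and their signs were mixed: fibroblasts were at -0.0936 (adjusted permutation p of 0.22), smooth muscle and pericytes at -0.03, elastic fibre at -0.02 and mesothelium at 0.06. It cannot be told apart from other causes: the test was to count against a mixture if no mesenchymal list passed, but that bound was wrong, since both alveolar lists passed and a missed threshold in 4 lists does not show that they did not shift.

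The glucocorticoid receptor motif matched 0.396% of distal peaks in replicate 1 (95% interval 0.364 to 0.430%) and 1.06% in replicate 2 (0.994 to 1.12%), a ratio of 2.67, while the flanks had 0.260% and 0.276%. Unequal lengths of the peak lists would leave shared peaks level, but the 463 shared distal peaks with the motif were relatively stronger in replicate 2 by a mean log2 of 0.92 (SE 0.04). The SE is over peaks within 1 pair of animals, which are not replicates, and measures no spread between animals. Before the correction for signal and GC content, 83.6% of these peaks lay above the median difference of all shared peaks. Base composition is argued against by 20 shuffled strings, of which the highest gave 0.084. A hypothesis is that the glucocorticoid receptor, or the mineralocorticoid, progesterone or androgen receptor with the same motif, was more active in the lung of replicate 2. Its test asked whether shared peaks around 16 known target genes shifted the same way: they lay above random genes by a mean log2 of 0.52 (random SD 0.05), in 16 of 16 genes (Mt1 and Mt2 share their 11 peaks, and 15 of 15 did so with 1 gene per 100 kb), with a two-sided permutation p of 2e-05, the smallest the permutations can give, and single genes ranged from 0.89 at Errfi1, 0.88 at Fkbp5 and 0.82 at Pdk4 to 0.04 at Per1. This is consistent with a more active receptor in 1 of 2 animals, but 12 of the 16 genes had no shared distal peak with the motif, it was found and tested on the same data, and stress, handling and time of day, which may move glucocorticoids, are not in the labels and stayed untested.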
